A study of Mus musculus with 4 samples.

How the data were processed

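RNA was measured in single cells of mouse spleen in 4 libraries with a probe-hybridization assay and 10x droplet capture. The deposited matrices hold raw UMI counts per gene and cell barcode, without normalization. The authors named Cell Ranger, DESeq2 and genome build mm10 in their processing notes without a version, role or order. The 4 matrices cover the same 19059 genes, of which 6 symbols occur more than once, and hold 25780 barcodes that had already been filtered to cells. The assay carries 13 mitochondrial genes. Gene positions came from GENCODE vM21 (GRCm38). Each library was its own group: control, PFOA, LCMV, and PFOA + LCMV.

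Cells needed at least 500 UMIs, 200 genes and at most 10% mitochondrial UMIs. The filter removed 0 control, 0 PFOA, 108 LCMV and 53 PFOA + LCMV cells, most of them over the mitochondrial limit. Doublets were called in each library with Scrublet (scanpy 1.11.5) at an expected rate of 5% and removed, 206, 175, 134 and 111 in the same order. The 24993 kept cells were scaled to 10000 UMIs per cell, log transformed and clustered together without batch correction. Of 2000 variable genes 1914 were used, since genes of the interferon, cell cycle and immediate early lists were left out so that these states did not define cell classes. Principal component analysis (30 components), a graph of 15 neighbours and Leiden clustering at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9) gave 43 clusters. Clusters were named by 230 marker genes of 17 classes, 227 of them measured. A marker counted when its level in the cluster was at least 1.5-fold that of the other clusters with 50 CPM added to both, with at least 20 UMIs. A class needed at least 3 markers, CD4 and CD8 T cells were told apart by a level ratio of 2, and clusters under 30 cells, or with more markers of another class among the 10 leading genes, stayed unnamed. A cluster with a median depth under 0.333 of that of its library and no own marker among the leading genes also stayed unnamed. The rule left 8 clusters unnamed, with 4.51%, 3.54%, 3.37% and 3.99% of cells in the 4 libraries. A first version of the rule, with 5 CPM added and 3 markers for gamma-delta T cells, left 12 clusters unnamed. These included clusters 4, 6 and 27, which are CD8 T cells under the final rule, and cluster 10, which is CD4 T cells. The first version was replaced after its clusters and class shares had been seen. In 87.8% of cells the class with the highest marker score of the single cell was the class of the cluster.

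Class shares are percentages of kept cells with exact Clopper-Pearson 95% intervals, and share ratios have approximate 95% intervals from the normal distribution of the log ratio. Where a count was 0, the limit is 3 counts of the total. Within a class, raw UMIs were summed over the cells of a library and expressed as CPM with exact Poisson 95% intervals. Log2 ratios used 0.5 UMI added to each sum, and a class needed at least 20 cells in each library compared. For genes at 0 in 1 library, list medians were also computed with a floor of 3 counts, and are printed where this moved them by more than 0.05. The 26 gene lists, with 618 genes of which 603 were measured, were fixed with the classes in which each is read, 73 list and class pairs in all. A member needed at least 40 UMIs over the 4 libraries in the class, or over the 2 libraries compared in medians within clusters and in the tests of explanations. Each list median of the main setting was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. The percentile describes these libraries and is no test between groups. Of 286 list medians 180 lay outside percentiles 2.5 to 97.5. Correlations were computed across genes with at least 200 UMIs. For the share of cells with a UMI, cells were thinned to 1500 UMIs and cells below that depth were left out. The background was the share in a class that should lack the gene, B cells for T cell genes and CD8 T cells for B cell genes. No p-value, standard error or count of changed genes was computed from cells, because the library is the replicate and each group had 1. The method was tested on simulated data made from the counts. A planted 2-fold change was recovered at log2 medians from 0.97 to 1.01 upward and from -1.02 to -0.98 downward. From 0 to 10 of 100 lists without a change lay outside the central 95%, by comparison and class. The simulated counts varied by counting error alone, without library differences, shared regulation of list genes or UMIs gathered in single cells. They therefore do not show how often real lists without a change fall outside that range.

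The comparisons, lists, markers, alternatives and the rule for naming genes were chosen before the data were examined. The rule named the 3 genes with the highest and the 3 with the lowest ratio per comparison in B, CD4 T and CD8 T cells, among genes with at least 200 UMIs and a 2-fold ratio. It also named up to 4 members of each list with the largest ratios, a panel of 25 genes, and the 3 genes per direction with the largest difference of PFOA ratios between infected and uninfected libraries. The mitochondrial limit, the minimum number of genes, the thinning depth, the marker fold, the cluster minimum and the graph settings were set after a first look at the files. The lists of marginal zone, immature and follicular B cells were chosen after the values were seen, as were the genes named from them. Alternatives changed the Leiden resolution (0.5 and 2.0), the variable genes, the doublets, the UMI minimum (1000), the source of cell classes, the scaling (median of ratios), the added UMI, the minimum of list members (200 and 10 UMIs), the depth (thinned cells), the average (mean of single-cell CPM) and the gene minimum of the correlations (1000 UMIs). Alternatives of list medians used 1000 random lists. Alternatives added after seeing the data left out cluster 6 from CD8 T cells, took CD8 T cells as a share of T cells, and used the first version of the naming rule. The barcode lists that came beside each matrix repeat its barcodes and were not used. T cell receptor and antibody sequences were not analysed here. Further tools were python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.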

Results

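Single-cell gene expression was measured in mouse spleen with a 10x probe-hybridization assay, which counts RNA molecules as UMIs (unique molecular identifiers) over 19059 genes. The 4 libraries formed a layout of PFOA exposure by LCMV infection with 1 library per group: control, PFOA, LCMV, and PFOA + LCMV. PFOA is perfluorooctanoic acid, a synthetic fluorinated surfactant, and LCMV is lymphocytic choriomeningitis virus, which infects mice naturally. The labels gave no PFOA dose, virus strain, day of infection or number of mice per library. Total depth was 20585317 UMIs in the control library, 15300422 in the PFOA library, 60012414 in the LCMV library and 68409690 in the PFOA + LCMV library. The median cell held 2596, 2308, 5573 and 5384 UMIs in the same order. After filtering, 6277, 5310, 6080 and 7326 cells remained. With 1 library per group no difference below has a replicate check, so "higher" and "lower" describe these 4 libraries and no test between groups was made. Intervals are 95% intervals, exact for shares, gene levels and gene ratios and approximate (log-normal) for share ratios, and cover counting error only. Those of gene levels and gene ratios treat UMIs as independent. They are therefore too narrow where a few cells hold much of a gene. Gene levels are CPM, the UMIs of a gene scaled to a common total of the summed UMIs of a cell class, and list medians are log2 ratios over the members of a gene list. A list median of the main setting given without a percentile lay outside the central 95% of random lists matched on expression. Medians at the floor, within clusters, among selected cells and in the tests of explanations were not placed among random lists. Medians under an alternative carry no percentile, whether or not they lay outside that range.

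The comparison of the LCMV library with the control library addressed the spleen's response to infection without PFOA. CD8 T cells, which kill virus-infected cells, were 11.6% of cells (10.8 to 12.4) in the control library and 25.3% (24.2 to 26.4) in the LCMV library, a ratio of 2.18 (2.01 to 2.36). Plasma cells, which secrete antibody, were 0.0956% and 4.67%, a ratio of 48.9 (21.8 to 109.6) that rested on 6 control cells. Germinal centre B cells, where antibody genes mutate, were 9.64-fold higher in the LCMV library, at 1.38% against 0.143%. Monocytes and macrophages were 6.88% against 2.37%, and neutrophils 4.28% against 1.98%. Stem and progenitor cells were 1.13% against 0.143%. CD4 T cells were lower, at 5.79% (5.22 to 6.41) against 15.6% (14.7 to 16.6), and B cells were 43.5% against 56.6%. NK cells were 1.12% against 3.31%, and gamma-delta and innate-like T cells 0.197% against 1.34%. The CD8 share ratio was 1.65 among cells with 1000 or more UMIs and 216 under a first version of the rule that names clusters. The 216 rested on 5 control cells, since that version left cluster 4, with 713 control cells, unnamed. Cluster 16, closest to CD8 T cells by its markers, stayed unnamed and held 222 control and 18 LCMV cells. Its leading genes were Trdc, a marker of gamma-delta and innate-like T cells, Eomes, Cd7 and Il2rb. The gamma-delta and innate-like share leaves these cells out and came from cluster 24 alone. No cluster met the naming rule for stromal or endothelial cells.

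**Figure D1:**
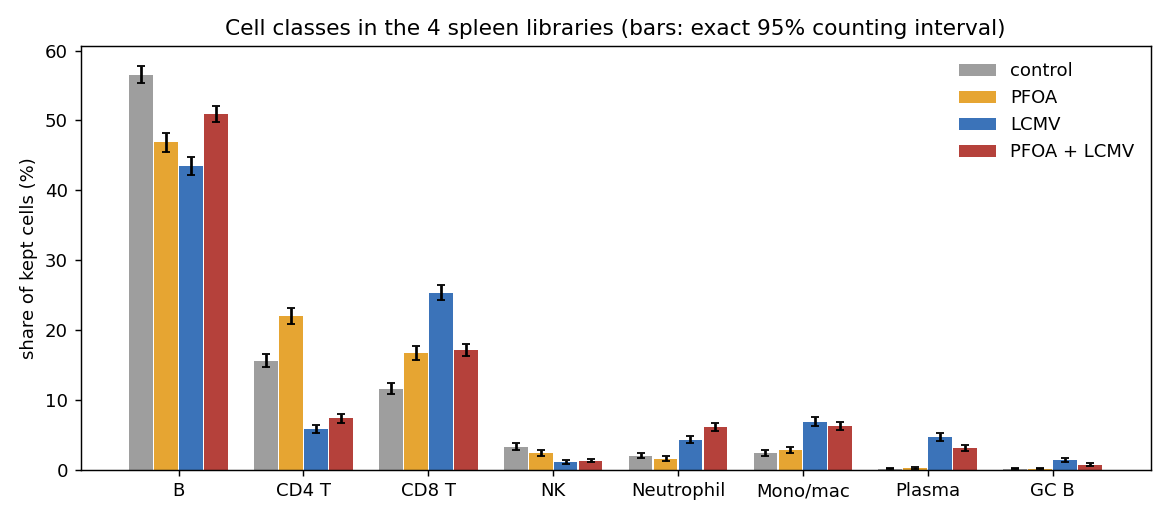
Share of kept cells (%) in 8 cell classes, with 1 bar per library and exact 95% binomial intervals. CD8 T cells stand at 25.3% in the LCMV library and 17.1% in the PFOA + LCMV library, and CD4 T cells are lower in both infected libraries.

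CD8 T cells of the LCMV library carried the genes of killer cells. Of the 27 measured cytotoxic effector genes 24 were at least 1.5-fold higher and 0 lower than in the control library, with a median log2 ratio of 4.14 (4.23 with genes at 0 set to the 3-count floor). Gzmb, the granzyme B gene (ENSMUSG00000015437, chromosome 14 from 56258838 to 56262260 on the minus strand, GRCm38), stood at 22.6 CPM (17.1 to 29.4) in the control library and 4809 CPM (4774 to 4844) in the LCMV library. In the control library 1 cell held 35.7% of the Gzmb UMIs, 75.0% of those of Klrg1 and 51.3% of those of Pdcd1. Klrg1, a marker of short-lived effector cells (ENSMUSG00000030114, chromosome 6 from 122270596 to 122282882 on the minus strand), was 64.8-fold higher, and Gzma, Gzmk, Ccl4 and Prf1 were 88.5-, 182-, 114- and 5.67-fold higher. Ifng, the interferon-gamma gene (ENSMUSG00000055170, chromosome 10 from 118441046 to 118445892 on the plus strand), had 3 UMIs in control CD8 T cells and 5871 in LCMV ones, a ratio with a counting interval of 110.5 to 1567, and 1 cell held 15.9% of the LCMV UMIs. Genes of inhibitory receptors were higher as well, with 12 of 16 exhaustion genes at least 1.5-fold higher and a median of 2.94 (3.01 at the floor). Pdcd1, which encodes PD-1, was 24.0-fold higher, at 383 CPM, and Lag3 78.3-fold higher. Among cells with 1000 or more UMIs the cytotoxic and exhaustion medians were 2.90 and 1.60. All 33 measured G2/M genes were at least 1.5-fold higher (median 2.40, or 3.32 with thinned cells and 3.41 with the mean of single-cell CPM). The proliferation gene Mki67 was 8.28-fold and Ccna2 10.6-fold higher, and 27 of 30 S phase genes were higher, with a median of 2.02 (1.30 without cluster 6). Genes of naive and memory T cells were lower in 17 of 18 cases (median -2.43). Tcf7 (ENSMUSG00000000782, chromosome 11 from 52252371 to 52283014 on the minus strand) was 8.36-fold lower, Il7r (ENSMUSG00000003882, chromosome 15 from 9505788 to 9530176 on the minus strand) 6.28-fold, Ccr7 14.0-fold and Igfbp4 45.0-fold lower. Glycolysis genes had a median of 0.94 and oxidative phosphorylation genes 0.45, and scaling by median of ratios would add 0.19 to log2 ratios of this class. In cells thinned to 1500 UMIs, Gzmb was seen in 83.2% of LCMV CD8 T cells and in 11.005% of LCMV B cells, the background from free RNA, with median depths of 7758 and 4127 UMIs before thinning. Without thinning the shares were 90.4% and 27.3%. In the control library Gzma was seen in 1.14% of thinned CD8 T cells and 1.34% of B cells, and Ifng in 0.142% and 0.336%. The control levels of these genes, on which their ratios rest, thus lay at the background. Most control CD8 T cells lay in cluster 4 and most LCMV ones in clusters 5, 6, 15 and 27.

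Interferon-stimulated genes, the first antiviral programme of most cells, were higher in the LCMV library in B, CD4 T, CD8 T and NK cells and in monocytes and macrophages. In B cells all 35 type I interferon genes were at least 1.5-fold higher, with a median log2 ratio of 2.45. The medians were 2.49 in CD4 T cells, 1.03 in CD8 T cells, 1.65 in monocytes and macrophages and 0.88 in NK cells, with 33, 26, 33 and 23 members at least 1.5-fold higher and 0 lower in each. Ifit3 (ENSMUSG00000074896, chromosome 19 from 34583531 to 34588731 on the plus strand) stood at 29.9 CPM in control B cells and 505 in LCMV ones, and Irf7 (ENSMUSG00000025498, chromosome 7 from 141262706 to 141266481 on the minus strand) at 72.9 and 800.5. Isg15 was 7.82-fold higher in B cells, 10.6-fold in CD4 T cells and 8.94-fold in monocytes and macrophages. Genes driven by interferon-gamma had medians of 3.57 in B cells, 2.19 (2.96 under the first version of the naming rule) in CD4 T cells, 0.69 in CD8 T cells and 3.78 in monocytes and macrophages. Iigp1, an interferon-induced GTPase, went from 0.818 CPM in control B cells to 283 in LCMV B cells and Gbp2 was 23.4-fold higher. The peptide-display genes of MHC class I were higher in 16 of 19 cases in B cells (median 0.90), with H2-Q7 at 4.66-fold and Psmb9 at 3.51-fold. MHC class I medians were 0.71 in CD4 T cells, 0.35 in CD8 T cells and 1.06 in monocytes and macrophages, and MHC class II genes in B cells had a median of 0.13 (percentile 97.3). In monocytes and macrophages Cxcl9 stood at 984 CPM against 10.7 CPM and Cxcl10 at 1006 against 6.44. Median-of-ratios scaling would add 0.27 to log2 ratios in this class and 0.11 in NK cells.

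Further genes differed in B cells, CD4 T cells and myeloid cells. B cell activation and germinal centre genes had a median of 0.63, with Cd86, a costimulatory gene, 4.24-fold and Tbx21, which is highest in NK cells, 3.63-fold higher. Fcer2a, the CD23 gene of mature B cells, was 5.14-fold lower, at 223 CPM against 1147. Cr2, the CD21 gene (ENSMUSG00000026616, chromosome 1 from 195136811 to 195176716 on the minus strand), was 2.37-fold lower. B cell receptor and identity genes had a median of -0.16 (percentile 38.7), with 20 of 23 members within 1.5-fold. CD4 T cells of the LCMV library showed T helper 1 and follicular helper genes at a median of 1.36, with 12 of 16 members higher, and at 0.36 among cells with 1000 or more UMIs and 0.20 under the first version of the naming rule. Pdcd1, Icos, Batf and Tnfrsf4 were 14.7-, 7.92-, 8.32- and 6.50-fold higher, and Tox2 and Cxcr3 were 7.29- and 3.73-fold higher. Regulatory T cell genes had a median of 0.83. In monocytes and macrophages the red pulp macrophage genes Cd163, Mrc1 and Slc40a1 were lower, with Cd163 at 1.23 CPM against 261, Mrc1 45.5-fold lower and Slc40a1 5.16-fold lower. Cluster 26, whose leading genes include Slc40a1 and Mrc1, held 7 of 418 LCMV and 71 of 149 control cells of this class. These ratios thus cannot separate the mix of clusters from a difference within cells. Of 21 phagocytosis and iron recycling genes 9 were lower and 2 higher, with a median of -0.26 (percentile 9.69), or 0.0060 with median-of-ratios scaling and -1.14 with the mean of single-cell CPM. Neutrophil granule genes had a median of 1.86 (1.502 at the floor), with Lcn2 6.20-fold and Mmp8 3.30-fold higher, and median-of-ratios scaling would add 0.49 there. In NK cells Gzmb was 5.32-fold and Klrg1 4.10-fold higher, in 68 LCMV and 208 control cells. Uninfected neutrophils lay in cluster 23 and infected ones in clusters 11 and 31, and uninfected monocytes and macrophages in clusters 26 and 30 against 17 and 19. B cells lay in clusters 0, 7, 12 and 20 without infection and in 1, 3 and 8 with it, and CD4 T cells in clusters 2 and 9, with cluster 10 shared.

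The comparison of the PFOA + LCMV library with the PFOA library addressed the same response under exposure. CD8 T cells again carried killer-cell genes, and their share of cells was 17.1% (16.3 to 18.0) with LCMV and 16.7% (15.7 to 17.7) without, a ratio of 1.03 (0.9503 to 1.11). This ratio was 0.836 at a Leiden resolution of 2.0 and 1.68 as a share of T cells. Under the first version of the naming rule it was 177, but that value rested on 3 PFOA cells. The CD8 shares leave out unnamed cluster 16, closest to CD8 T cells, with 57 PFOA + LCMV and 162 PFOA cells. CD4 T cells were 3.01-fold lower, at 7.33% against 22.03%. Plasma cells were 3.13% against 0.264%, a ratio of 11.9 (6.92 to 20.3). Germinal centre B cells were 5.07-fold, neutrophils 3.95-fold and monocytes and macrophages 2.27-fold higher. B cells were 51.0% against 46.9%, NK cells 1.28% against 2.34%, and gamma-delta and innate-like T cells 0.232% against 1.75%. In CD8 T cells 23 of 27 cytotoxic genes were at least 1.5-fold higher (median 3.93), and Gzmb was 375-fold, Gzma 292-fold, Klrg1 103-fold, Ccl4 111-fold and Ifng 43.3-fold higher. These folds rested on 36, 14, 9, 6 and 8 UMIs in the PFOA library, with counting intervals of 57.4 to 239 for Klrg1 and 23.3 to 107 for Ifng, and 1 PFOA cell held 77.8% of Klrg1 and 62.5% of Ifng UMIs. In thinned PFOA CD8 T cells Gzma, Klrg1 and Ifng were seen in 0.473%, 0.118% and 0.118%, near B cell backgrounds of 0.523%, 0.105% and 0.157%. The cytotoxic median was 2.68 among cells with 1000 or more UMIs and 2.98 with classes from single-cell marker scores. Exhaustion genes had a median of 1.80 (2.60 with classes from single-cell marker scores), with Pdcd1 23.3-fold and Lag3 22.5-fold higher. All 33 G2/M genes were higher (median 3.04), with Plk1 at 15.2-fold, and S phase genes had a median of 1.64. These medians were 5.29 and 2.51 with classes from single-cell marker scores and 2.46 and 0.83 without cluster 6. Naive and memory genes were lower in 16 of 18 cases (median -1.89), with Tcf7 5.02-fold, Il7r 5.12-fold and Igfbp4 11.4-fold lower. The naive and memory median was -1.20 with thinned cells, -1.28 with the mean of single-cell CPM and -1.12 without cluster 6. Median-of-ratios scaling would add 0.15 to log2 ratios of CD8 T cells, 0.28 to those of monocytes and macrophages and 0.50 to those of neutrophils. Most CD8 T cells lay in cluster 4 in the PFOA library and in clusters 5, 6 and 15 in the PFOA + LCMV library.

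Interferon genes were higher in B cells of the PFOA + LCMV library too, where all 35 members were at least 1.5-fold higher (median 2.10). The medians were 2.20 in CD4 T cells, 1.17 in CD8 T cells, 1.70 in monocytes and macrophages and 1.47 in NK cells (1.53 at the floor). In B cells Ifit3 was 16.0-fold, Irf7 8.37-fold and Gbp2 16.1-fold higher. Interferon-gamma genes had medians of 2.92 in B cells, 2.21 (2.91 under the first version of the naming rule) in CD4 T cells, 0.76 (1.37 with thinned cells or without cluster 6) in CD8 T cells and 3.64 in monocytes and macrophages. MHC class I genes in B cells had a median of 0.95, with H2-Q7 5.00-fold and B2m 3.02-fold higher. Fcer2a was 2.82-fold lower in B cells, while Cr2 was within 1.5-fold, at 267 CPM against 306. T helper 1 and follicular helper genes in CD4 T cells had a median of 1.62 (0.48 among cells with 1000 or more UMIs), with Il21 18.7-fold, Pdcd1 8.99-fold and Icos 5.53-fold higher. Cholesterol and fatty acid synthesis genes were lower in CD4 T cells in 15 of 25 cases (median -0.83), with Idi1 4.44-fold lower. The same list had a median of -0.052 (percentile 37.4) without PFOA. Neutrophil granule genes had a median of 2.83 (2.16 at the floor and 1.501 with members of 10 or more UMIs), with Lcn2 8.19-fold and Mmp8 7.02-fold higher. Camp, Ngp and Ltf had 1, 2 and 0 UMIs in PFOA neutrophils. In control neutrophils they had 561, 722 and 343, of which 1 cell held 99.8%, 99.2% and 100%. A comparison of this median with that without PFOA is limited by such genes. In monocytes and macrophages Cd163 stood at 0.641 CPM against 328, and Cxcl9 at 841 against 21.6. Cluster 26 held 8 of 458 PFOA + LCMV and 73 of 146 PFOA cells of this class. For Cd163 the mix of clusters therefore cannot be told apart from a difference within cells.

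**Figure D2:**
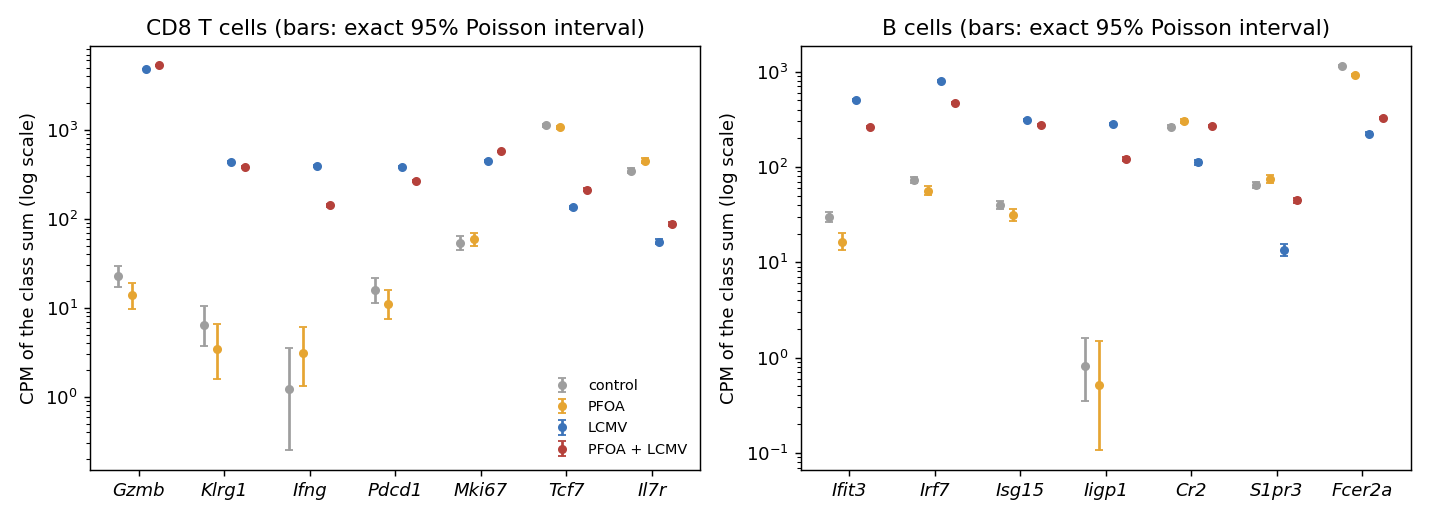
CPM on a log scale of 7 genes in CD8 T cells and 7 genes in B cells, with 1 point per library and exact 95% Poisson intervals. Gzmb lies near 4809 and 5271 CPM in the infected libraries, while Ifng is 392 in the LCMV and 142 in the PFOA + LCMV library.

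The comparison of the PFOA library with the control library addressed exposure in the uninfected spleen. B cells were lower and T cells higher in the PFOA library: B cells were 46.9% (45.5 to 48.2) against 56.6% (55.3 to 57.8), CD4 T cells 22.03% against 15.6%, and CD8 T cells 16.7% against 11.6%. The CD8 share ratio was 1.44. It was 0.709 under the first version of the naming rule, but that version left cluster 4 unnamed. It thus set 3 PFOA cells against 5 control cells. The share of T cells that were CD8 T cells was alike, at 41.2% (39.1 to 43.3) in the PFOA library and 40.6% (38.4 to 42.9) in the control library. These CD8 shares leave out unnamed cluster 16, closest to CD8 T cells, with 162 PFOA and 222 control cells. NK cells were 2.34% against 3.31%, and neutrophils 1.54% against 1.98%, a ratio whose interval spans 1 (0.593 to 1.03). Erythroid cells were 0.0637% (0.0174 to 0.163) of control cells, from 4 cells, and 0 of 5310 PFOA cells lay in the erythroid cluster. The PFOA limit was 0.0565% by 3 counts and 0.0694% by the exact interval, which overlaps the control interval. Interferon-stimulated genes, which resting cells carry at a low level, were slightly lower in the PFOA library. The medians were -0.14 in B cells, -0.25 in CD4 T cells, -0.19 in CD8 T cells and -0.19 in monocytes and macrophages, and 4, 8, 1 and 3 members reached 1.5-fold lower. In B cells Ifit3 was 1.81-fold and Rsad2 1.87-fold lower, and in CD4 T cells Ifi27l2a was 1.59-fold and Irf7 1.40-fold lower. In NK cells the interferon median was -0.021 (percentile 31.7). RNA of some other classes was also lower in the PFOA library. In CD4 T cells Cd79a stood at 107 against 198 CPM and S100a8 at 47.6 against 100. Lyz2 was close there, at 19.8 against 21.4 CPM, and Cd3e in B cells was higher, at 21.4 against 17.7. Whether less free RNA accounts for the small interferon medians was not tested. Targets of PPAR-alpha, a fatty acid sensor that PFOA can activate, had medians below the random range in B cells and in monocytes and macrophages and within it in CD4 and CD8 T cells. Their medians were -0.090 in B cells, -0.0083 (percentile 56.7) in CD4 T cells, -0.067 (percentile 13.9) in CD8 T cells and -0.23 in monocytes and macrophages, and that of CD4 T cells was 0.0058 with median-of-ratios scaling. All 28 members lay within 1.5-fold in B cells and 4 of 30 were lower in monocytes and macrophages, Cpt1a was at 78.1 against 88.6 CPM, and in CD8 T cells Acot2 was 1.43-fold higher. Pdk4, which responds to PPAR-alpha in liver, had 0 UMIs in B, CD4 T and CD8 T cells of both libraries, and 1 UMI in B cells of the PFOA + LCMV library.

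CD4 T cells of the PFOA library had higher levels of a pair of growth-restraint and death genes. Ddit4, an inhibitor of mTOR signalling, stood at 1275 CPM (1234 to 1317) against 441 CPM (417 to 467), a ratio of 2.89. Bbc3, which encodes the death factor PUMA, was 2.60-fold higher in CD4 T cells and 2.12-fold higher in CD8 T cells. The p53 and apoptosis list as a whole had a median of 0.10 (percentile 96.2) in CD4 T cells. Cholesterol synthesis genes had a median of 0.32 in CD4 T cells, with Idi1 1.79-fold, Mvd 1.68-fold, Sqle 1.54-fold and Cyp51 1.54-fold higher, but Scd1, which is highest in B cells, 1.77-fold lower. S phase genes were lower in CD4 T cells (median -0.47) and higher in CD8 T cells (median 0.41), and both directions reversed, to 0.43 and -0.43, when classes came from single-cell marker scores. Without cluster 6 the CD8 median was -0.055. T helper 1 and follicular helper genes had a median of -0.27 in CD4 T cells, with Cxcr3, which is highest in CD8 T cells, 1.67-fold lower. In CD8 T cells cytotoxic genes had a median of -0.16, from low levels such as 5.39 against 18.2 CPM for Gzma. A Gzma UMI was seen in 0.473% of thinned PFOA and 1.14% of thinned control CD8 T cells. The B cell backgrounds were 0.523% and 1.34%, so the Gzma difference cannot be told apart from free RNA. Naive and memory genes in CD8 T cells had a median of -0.056 (percentile 8.39). Trnp1, a nuclear protein gene, was 4.64-fold higher in CD8 T cells, at 100.2 CPM. In B cells Hsph1, a heat shock gene, was 2.08-fold and Ston1 6.90-fold higher, and Cplx2 was 2.22-fold lower. Genes of immature B cells, a list chosen after the values were seen, had a median of -0.54 (-0.35 at the floor), with Cd93, which is highest in monocytes and macrophages, 1.76-fold and Sox4 1.45-fold lower. Cluster 20, which Fam129c, Vpreb3 and Spib lead, held 8.82% of B cells in the control library and 2.69% in the PFOA library. The granule gene Camp had 561 UMIs in control neutrophils, nearly all in 1 cell (99.8%), against 1 in PFOA ones, beside a granule list median of -0.33 in neutrophils. In control neutrophils 1 cell also held 99.2% of Ngp, 100% of Ltf and 98.7% of Chil3 UMIs.

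The comparison of the PFOA + LCMV library with the LCMV library addressed how exposure bears on the infected spleen, the subject of the series title. CD8 T cells, the main killers of LCMV-infected cells, were 17.1% (16.3 to 18.0) of the PFOA + LCMV library against 25.3% (24.2 to 26.4) of the LCMV library, 1.48-fold lower. As a share of T cells they were 69.4% (67.2 to 71.5) against 80.9% (79.0 to 82.6). Unnamed cluster 16, with 57 PFOA + LCMV and 18 LCMV cells, is in neither share. Germinal centre B cells were 2.07-fold lower, at 0.669% (0.495 to 0.883) against 1.38% (1.103 to 1.71), and plasma cells 1.49-fold lower, at 3.13% against 4.67%. Plasmacytoid dendritic cells, a source of type I interferon, were 0.177% against 0.378%. This ratio of 0.469 (0.238 to 0.925) rested on 13 and 23 cells. Neutrophils were 1.43-fold higher (1.23 to 1.66), CD4 T cells 1.27-fold and B cells 1.17-fold higher. NK cells were 1.28% against 1.12% with an interval of the ratio that spans 1 (0.841 to 1.56), and monocytes and macrophages were 6.25% against 6.88%.

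In CD8 T cells of the PFOA + LCMV library 7 of 27 cytotoxic genes were at least 1.5-fold lower than in the LCMV library, 0 were higher and 20 lay between (median -0.37). Within clusters 5, 6, 15 and 27 the cytotoxic medians were -0.045, -0.19, 0.092 and 0.074, and the exhaustion medians -0.14, -0.24, 0.46 and 0.46. These lists were not left out of the clustering, so such medians cannot separate the mix of clusters from a difference within cells. Ifng was 2.76-fold lower, at 142 CPM (136 to 148) against 392 (382 to 402). Ccl3 was 2.01-fold, Ccl4 1.91-fold and the homing receptor gene Cxcr6 1.82-fold lower. Gzmb was 1.096-fold higher, Gzma and Gzmk were 1.003- and 1.02-fold, and Prf1 and Klrg1 stood at 0.795 and 0.876 of the LCMV level. In thinned cells Ifng was seen in 10.5% against 20.8% of CD8 T cells, with B cell backgrounds of 0.512% and 1.42%, and Klrg1 in 28.8% against 38.4%, with backgrounds of 1.08% and 1.11%. Median depths before thinning were 8227 and 7758 UMIs in CD8 T cells and 4500 and 4127 in B cells, and unthinned shares were 37.4% and 50.3% for Ifng and 47.3% and 59.9% for Klrg1. Gzmb was seen in 66.8% against 83.2% of thinned CD8 T cells (backgrounds 10.6% and 11.005%). Exhaustion genes had a median of -0.25, with Pdcd1 1.45-fold, Lag3 1.51-fold and the activation-induced gene Nr4a2 2.25-fold lower. Naive and memory genes were higher in 8 of 18 cases and lower in 0 (median 0.39), with Igfbp4 3.63-fold, Dapl1 3.61-fold, Id3 2.55-fold, Il7r 1.59-fold and Tcf7 1.57-fold higher. G2/M genes had a median of 0.41, with Plk1 1.56-fold and Mki67 1.29-fold higher, but without cluster 6, whose leading genes include histone genes, the median was 0.0094. S phase genes had a median of 0.16, which was -0.21 without cluster 6 and -0.18 under the first version of the naming rule. Most CD8 T cells lay in cluster 5 in the LCMV library and in clusters 5, 6 and 15 in the PFOA + LCMV library. Clusters 5, 6, 15 and 27 held 31.7%, 34.8%, 26.7% and 6.14% of them in the PFOA + LCMV library. In the LCMV library these shares were 59.0%, 27.3%, 9.09% and 4.48%. Unfolded protein response genes had a median of 0.25, with 20 of 20 members within 1.5-fold. Ccl1 had 846 UMIs in LCMV CD8 T cells, 89.0% of them in 5 cells, against 9 in PFOA + LCMV ones, and 99.1% of Penk UMIs came from 1 PFOA + LCMV cell. Genes of other classes differed too in this class: the B cell gene Cd79a stood at 152 against 71.0 CPM, and Cd74 and H2-Ab1, highest in dendritic cells, were 2.04- and 2.03-fold higher. The antibody gene Ighg3 was 11.5-fold lower, but 1 LCMV cell held 89.3% of its UMIs there.

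The type I interferon programme was lower in B cells and CD4 T cells of the PFOA + LCMV library. In B cells no member was 1.5-fold higher and 9 of 35 were lower (median -0.41), and in CD4 T cells 12 were lower (median -0.45). Ifit3 was 1.91-fold lower in B cells, at 264 CPM (257 to 272) against 505 (492 to 517), and 1.82-fold lower in CD4 T cells. Irf7 was 1.70-fold and Ifi44 2.03-fold lower in B cells, and Isg15 1.65-fold and Rsad2 1.84-fold lower in CD4 T cells. The medians were nearer 0 in CD8 T cells, at -0.031 (percentile 2.96) and 0.082 with thinned cells, and in monocytes and macrophages, at -0.12. In NK cells the median was higher, at 0.48 over 30 members, with Isg15 at 221 against 96.5 CPM, from 94 and 68 cells. B cell RNA was also higher in these NK cells, with Cd79a at 321 against 65.2 CPM and Cd74 at 1798 against 780.2 CPM. Among NK cells without a Cd79a UMI, 52 and 53 cells, the interferon median was 0.49. Interferon-gamma genes in B cells had a median of -0.39, with Iigp1 2.34-fold, Tgtp1 1.52-fold and Cd274, the PD-L1 gene, 1.51-fold lower. All 19 MHC class I genes lay within 1.5-fold (median -0.013, percentile 31.9). MHC class II genes in B cells had a median of 0.15.

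**Figure D3:**
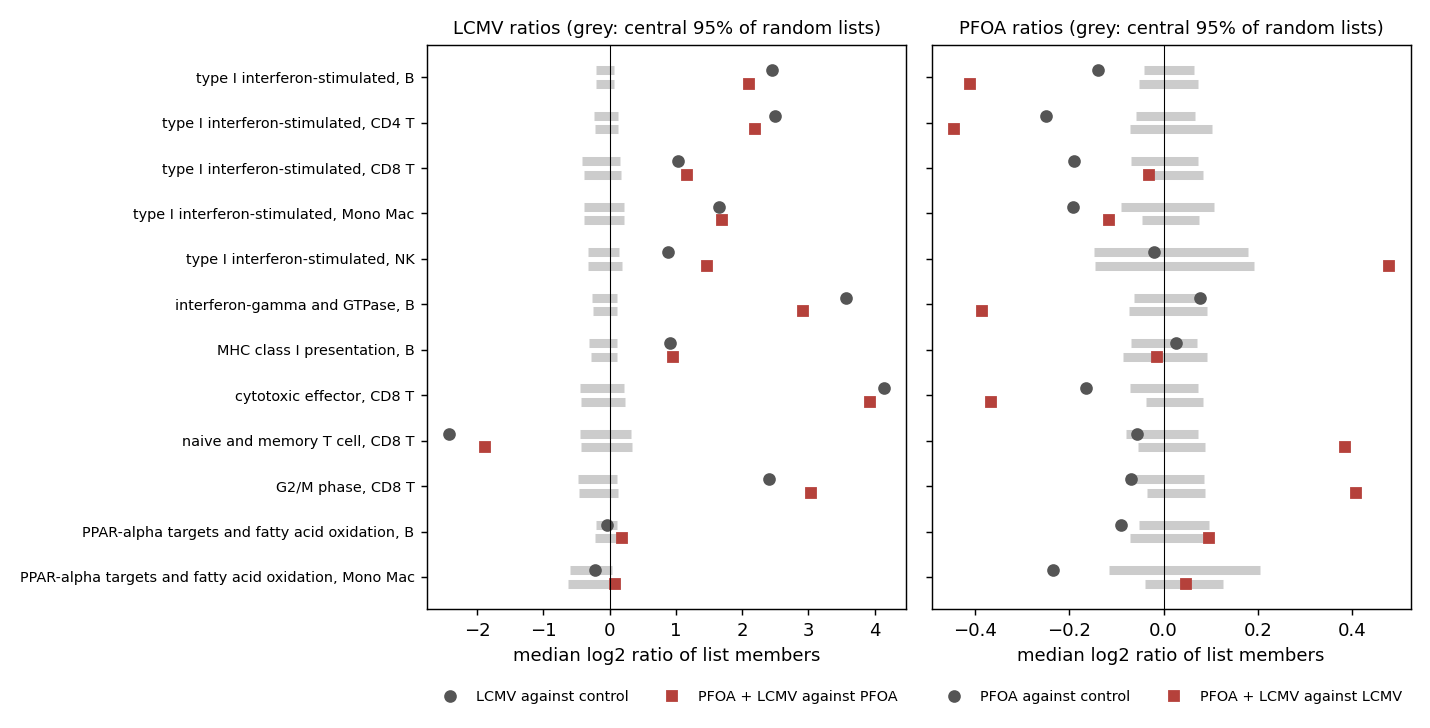
Median log2 ratio of 12 list and class pairs for the LCMV ratios and the PFOA ratios, with grey bars for the central 95% of matched random lists. The interferon medians of B and CD4 T cells lie at -0.41 and -0.45 for PFOA + LCMV against LCMV, and that of NK cells at 0.48.

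B cells of the PFOA + LCMV library had higher levels of genes of marginal zone B cells, which answer blood-borne antigens. This list was chosen after the values were seen, and its median was 0.73, with 5 of 8 members higher. For the PFOA library against the control library its median was 0.25, with all 8 members within 1.5-fold. The LCMV medians of this list were -0.71 without PFOA and -0.33 with it. Cr2 was 2.40-fold higher, at 267 CPM (259.9 to 274) against 111 (106 to 117), close to the control level of 264. S1pr3 (ENSMUSG00000067586, chromosome 13 from 51408639 to 51422797 on the plus strand), at a like level in monocytes and macrophages, was 3.29-fold higher, Tnfrsf13b 2.33-fold, Dtx1, which is highest in gamma-delta and innate-like T cells, 1.72-fold and Tspan15, which is highest in monocytes and macrophages, 7.55-fold higher. Thinned B cells with a Cr2 UMI were 26.1% against 12.2%, with CD8 T cell backgrounds of 1.68% and 0.390%. Without thinning they were 52.3% and 27.5%, at median depths of 4500 and 4127 UMIs in B cells and 8227 and 7758 in CD8 T cells. Follicular B cell genes, also chosen after the values were seen, had a median of 0.050 (percentile 73.2), with Fcer2a 1.46-fold higher. Immature B cell genes had a median of -0.996 (-0.17 with thinned cells), with Sox4 and Cd93 2.01- and 1.99-fold lower. B cell activation genes had a median of -0.30, with Cd86 1.48-fold lower. Plasma cells had an antibody secretion median of 0.18 (percentile 75.6), with Ighg1 1.75-fold and Igha 1.85-fold lower and Txndc5 1.75-fold higher, but 1 cell held 73.5% of the LCMV UMIs of Ighg1 and 74.5% of those of Igha. Median-of-ratios scaling would shift plasma cell log2 ratios by -0.13. Cluster 3, whose leading genes include Cr2 and Fcrl5, held 34.6% (33.0 to 36.1) of B cells in the PFOA + LCMV library against 15.6% (14.3 to 17.1) in the LCMV library, and cluster 1 held 47.4% against 67.9%.

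In CD4 T cells of the PFOA + LCMV library 3 of 16 T helper 1 and follicular helper genes were lower, 2 higher and 11 within 1.5-fold (median -0.089, percentile 8.04). Tnfrsf4, which encodes OX40, was 2.34-fold lower, Batf 1.77-fold, Pdcd1 1.72-fold and Il1r2, which is highest in neutrophils, 9.59-fold lower. Maf was 1.81-fold and Il21 1.49-fold higher. Regulatory T cell genes had a median of -0.47, with 5 of 12 members lower. Cholesterol synthesis genes had a median of -0.42, with Idi1 2.63-fold and Sqle 2.15-fold lower. Glycolysis genes had a median of -0.44, with Hk2, which is highest in plasma cells, 3.79-fold lower, and S phase genes -0.93, but under the first version of the naming rule these were 0.10 and -0.024. Ddit4 and Bbc3 were again higher, 2.66- and 3.52-fold, whereas Bbc3 in CD8 T cells was at 1.03-fold. In neutrophils inflammatory NF-kB genes were lower in 8 of 18 cases (median -0.56), with Tnf 2.12-fold, Cxcl2 2.75-fold and Icam1 2.02-fold lower. In monocytes and macrophages these genes had a median of -0.33, with Tnf 1.71-fold, Ptgs2 2.53-fold and Il1b, which is highest in neutrophils, 3.26-fold lower. Cxcl10 was 1.69-fold lower there, while Cxcl9 stood at 0.855 of the LCMV level. PPAR-alpha targets had medians of 0.096 in B cells, 0.037 (percentile 72.5) in CD4 T cells, 0.023 (percentile 37.7) in CD8 T cells and 0.048 (percentile 55.7) in monocytes and macrophages. Median-of-ratios scaling gave -0.0055 in CD8 T cells and -0.0048 in monocytes and macrophages.

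The 2 by 2 layout also asked whether the PFOA difference was alike with and without virus. Across genes, which are not independent replicates, the LCMV ratios with and without PFOA had a Pearson r of 0.867 in B cells (9332 genes), 0.827 in CD4 T cells (7570 genes) and 0.929 in CD8 T cells (9114 genes), with Spearman rho of 0.762, 0.737 and 0.915. The PFOA ratios with and without LCMV had an r of 0.127, 0.0565 and 0.0368, with rho of 0.0956, 0.0556 and 0.0478. PFOA ratios also spread less, with log2 standard deviations of 0.249 and 0.261 in B cells against 0.638 and 0.669 for LCMV ratios. These were 0.326 and 0.245 against 0.642 and 0.696 in CD4 T cells, and 0.279 and 0.366 against 1.16 and 1.22 in CD8 T cells. Counting error weighs more on a small spread, so the low r does not show that PFOA acted differently under infection. The direction was the same for 78.5%, 76.9% and 89.0% of genes in the LCMV ratios and for 52.9%, 51.5% and 52.2% in the PFOA ratios. The paired comparisons shared no library. As a median over members of the difference of log2 ratios, infected minus uninfected, the interferon list was -0.13 in B cells and -0.22 in CD4 T cells, the interferon-gamma list -0.58 in B cells, and the naive list 0.33 in CD8 T cells. Single genes of CD4 T cells with a large difference were Angptl2, at 4.03, and Ramp3 and Fosl2, which is highest in neutrophils, at -3.69 and -3.21. None of these differences was tested.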

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

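The 9 results below were singled out because the PFOA difference went in opposite directions without and with LCMV, and none of these differences was tested. The value under the first version of the naming rule comes from an alternative added after the data were seen. PPAR-alpha target genes in B cells had medians of -0.090 without and 0.096 with LCMV, a difference between the medians of 0.19 (log2, infected minus uninfected, also in the next values). S phase genes in NK cells had medians of -0.38 and 0.85, a difference of 1.23, and the first median was 0.00222 with thinned cells. As a median over members this difference was 1.28, or 0.56 with thinned cells and 0.46 with classes from single-cell marker scores. Cholesterol and fatty acid synthesis genes in CD4 T cells had medians of 0.32 and -0.42, a difference of -0.74. Granulocyte granule genes in monocytes and macrophages had medians of -0.30 and 0.42, a difference of 0.72, and the first was 0.022 with thinned cells and -0.99 with classes from single-cell marker scores. Immediate early and dissociation stress genes in CD4 T cells had medians of 0.092 and -0.16, a difference of -0.26, and the first changed sign under 3 alternatives. Interferon-gamma genes in B cells had medians of 0.079 and -0.39, a difference of -0.46. The B cell share ratio of PFOA to no PFOA was 0.829 without and 1.17 with LCMV, and the infected ratio was 1.41 times the uninfected one. The plasma cell share ratios were 2.76 and 0.669, a ratio of 0.243 between them, with 6 control and 14 PFOA plasma cells. The CD8 T cell share ratios were 1.44 and 0.676, a ratio of 0.471 between them. The first reversed to 0.709 under the first version of the naming rule, but on 3 PFOA and 5 control cells alone.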

How the results depend on the processing

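Alternatives added after seeing the data were the one without cluster 6, the share of T cells and the first version of the naming rule, and the others had been fixed beforehand. In brackets, LCMV stands for the LCMV library against the control library, LCMV under PFOA for PFOA + LCMV against PFOA, PFOA for PFOA against control, PFOA under LCMV for PFOA + LCMV against LCMV, and interaction for the difference of PFOA ratios, infected minus uninfected. List values are median log2 ratios, macrophages include monocytes, and a change of sign counts as reversed only where the reported median lay outside the central 95% of random lists or the share ratio's interval left out 1. Of the values that lead a comparison, 733 list medians and 163 share ratios under the alternatives moved by less than the spread of random lists or stayed within the counting interval, 130 and 22 moved further, and 3 and 1 reversed. Of the other list medians 2561 stayed, 263 moved and 27 reversed, and of the other class shares 178 stayed and 46 moved. Of 12 correlations 11 stayed within 0.1. The interferon list stayed higher in both infected libraries in B, CD4 T and CD8 T cells, and lower in B and CD4 T cells for PFOA under LCMV, under every alternative run. The CD8 share ratio for PFOA under LCMV stayed between 0.580 and 0.858 under every alternative run. Moved values that lead a comparison and all reversed values are given next by setting. Under the first version of the naming rule the clusters were the same, but cluster 10 dropped out of CD4 T cells and clusters 4, 6 and 27 out of CD8 T cells. Changes in these classes under that version come from leaving out those cells, and the cause of the other changes was not tested. At Leiden resolution 0.5, the CD8 share ratio moved to 1.74 (LCMV), 0.927 (LCMV under PFOA) and 1.30 (PFOA). At Leiden resolution 2.0, the CD8 share ratio moved to 1.72 (LCMV) and 0.836 (LCMV under PFOA). With doublets kept, the cytotoxic list in CD8 T cells moved to -0.23 (interaction) and the G2/M list in CD8 T cells to 0.58 (interaction). Among cells with 1000 or more UMIs, the CD4 share ratio moved to 0.319 (LCMV) and 0.286 (LCMV under PFOA) and the CD8 share ratio to 1.65 (LCMV), 0.851 (LCMV under PFOA) and 1.30 (PFOA). The interferon list in CD4 T cells moved to -0.15 (PFOA) and -0.35 (PFOA under LCMV) and the cytotoxic list in CD8 T cells to 2.90 (LCMV) and 2.68 (LCMV under PFOA). The exhaustion list in CD8 T cells moved to 1.60 (LCMV) and -0.078 (interaction) and the S phase list in CD4 T cells to 0.59 (LCMV), 0.29 (LCMV under PFOA), -0.052 (PFOA) and -0.46 (PFOA under LCMV). The G2/M list in CD8 T cells moved to 2.71 (LCMV) and 3.39 (LCMV under PFOA). Among cells with 1000 or more UMIs, the glycolysis list in CD4 T cells reversed to -0.080 (LCMV, from 0.88) and -0.075 (LCMV under PFOA, from 0.35). With classes from single-cell marker scores, the B share ratio moved to 0.658 (LCMV) and 1.32 (PFOA under LCMV) and the neutrophil share ratio to 2.67 (LCMV). The interferon list in CD4 T cells moved to 2.15 (LCMV), -0.30 (PFOA under LCMV) and -0.082 (interaction) and the cytotoxic list in CD8 T cells to 3.33 (LCMV) and 2.98 (LCMV under PFOA). The exhaustion list in CD8 T cells moved to 2.60 (LCMV under PFOA) and 0.10 (PFOA) and the S phase list in CD4 T cells to 1.74 (LCMV), -0.66 (PFOA under LCMV) and -0.94 (interaction). The G2/M list in CD8 T cells moved to 2.72 (LCMV), 5.29 (LCMV under PFOA), -2.00 (PFOA) and 2.51 (interaction) and the cholesterol list in CD4 T cells to -0.26 (PFOA under LCMV) and -0.49 (interaction). With classes from single-cell marker scores, the S phase list in CD4 T cells reversed to 0.43 (PFOA, from -0.47) and the S phase list in CD8 T cells to -0.43 (PFOA, from 0.41) and 0.60 (interaction, from -0.26). The G2/M list in B cells reversed to 0.33 (PFOA, from -0.15) and -0.36 (interaction, from 0.20) and the G2/M list in CD4 T cells to 0.64 (PFOA, from -0.57). The oxidative phosphorylation list in CD4 T cells reversed to 0.017 (PFOA, from -0.047) and the NRF2 list in macrophages to 0.049 (interaction, from -0.14). The stress list in CD4 T cells reversed to -0.054 (PFOA, from 0.092). With median-of-ratios scaling, the NF-kB list in neutrophils moved to 0.81 (LCMV) and 0.33 (LCMV under PFOA) and the antibody secretion list in plasma cells to 0.052 (PFOA under LCMV). The granule list in neutrophils moved to 2.35 (LCMV). With no UMI added, the interferon-gamma list in B cells moved to 3.37 (LCMV) and the granule list in neutrophils to 2.16 (LCMV under PFOA). With members of 200 or more UMIs, the S phase list in CD4 T cells moved to 0.83 (LCMV), 0.41 (LCMV under PFOA), -0.21 (PFOA) and -0.64 (PFOA under LCMV). With members of 200 or more UMIs, the G2/M list in B cells reversed to -0.0082 (interaction, from 0.20). With members of 10 or more UMIs, the granule list in neutrophils moved to 1.28 (LCMV), 1.501 (LCMV under PFOA) and 0.22 (PFOA under LCMV). With members of 10 or more UMIs, the stress list in CD4 T cells reversed to -0.014 (PFOA, from 0.092) and the immature B cell list in B cells to 0.15 (LCMV, from -0.48). With each cell thinned to 1500 UMIs, the interferon list in B cells moved to 2.42 (LCMV under PFOA) and -0.23 (interaction) and the interferon list in CD4 T cells to 2.24 (LCMV). The interferon list in CD8 T cells moved to 1.66 (LCMV under PFOA), 0.082 (PFOA under LCMV) and 0.34 (interaction) and the cytotoxic list in CD8 T cells to 4.31 (LCMV under PFOA), -0.090 (PFOA), -0.46 (PFOA under LCMV) and -0.35 (interaction). The exhaustion list in CD8 T cells moved to 3.60 (LCMV), 0.16 (PFOA) and -0.43 (PFOA under LCMV) and the naive and memory list in CD8 T cells to -1.98 (LCMV), -1.20 (LCMV under PFOA), 0.65 (PFOA under LCMV) and 0.55 (interaction). The S phase list in CD4 T cells moved to 0.37 (LCMV), 0.47 (LCMV under PFOA), -0.076 (PFOA), -0.21 (PFOA under LCMV) and -0.19 (interaction) and the G2/M list in CD8 T cells to 3.32 (LCMV), 3.71 (LCMV under PFOA), 0.30 (PFOA under LCMV) and 0.31 (interaction). The NF-kB list in neutrophils moved to -0.84 (PFOA under LCMV) and the granule list in neutrophils to -0.11 (PFOA) and 0.15 (PFOA under LCMV). The marginal zone list in B cells moved to 0.55 (PFOA under LCMV) and 0.30 (interaction) and the Pearson r of LCMV ratios in CD4 T cells to 0.717. With each cell thinned to 1500 UMIs, the MHC class II list in macrophages reversed to -0.042 (PFOA, from 0.21) and 0.021 (interaction, from -0.22) and the cytotoxic list in CD4 T cells to 0.083 (PFOA under LCMV, from -0.30). The S phase list in NK cells reversed to 0.0022 (PFOA, from -0.38) and the PPAR-alpha list in CD8 T cells to -0.0051 (LCMV, from 0.21). The cholesterol list in macrophages reversed to 0.025 (interaction, from -0.30) and the stress list in CD4 T cells to -0.021 (PFOA, from 0.092). The granule list in macrophages reversed to 0.022 (PFOA, from -0.30). With the mean of single-cell CPM, the interferon list in B cells moved to -0.21 (PFOA) and the interferon list in CD4 T cells to 2.25 (LCMV) and -0.059 (interaction). The interferon list in CD8 T cells moved to 1.63 (LCMV under PFOA), 0.045 (PFOA under LCMV) and 0.22 (interaction) and the interferon-gamma list in B cells to 0.16 (PFOA). The cytotoxic list in CD8 T cells moved to 4.61 (LCMV), -0.088 (PFOA) and -0.44 (interaction) and the exhaustion list in CD8 T cells to 0.19 (PFOA). The naive and memory list in CD8 T cells moved to -1.95 (LCMV), -1.28 (LCMV under PFOA), 0.60 (PFOA under LCMV) and 0.55 (interaction) and the S phase list in CD4 T cells to 0.80 (LCMV), -0.15 (PFOA), -0.35 (PFOA under LCMV) and -0.079 (interaction). The G2/M list in CD8 T cells moved to 3.41 (LCMV), 3.93 (LCMV under PFOA), 0.028 (PFOA), 0.28 (PFOA under LCMV) and 0.29 (interaction) and the PPAR-alpha list in macrophages to 0.36 (interaction). The granule list in neutrophils moved to 0.14 (PFOA under LCMV). Without cluster 6, the interferon list in CD8 T cells moved to 1.36 (LCMV), 1.72 (LCMV under PFOA), 0.056 (PFOA under LCMV) and 0.16 (interaction) and the cytotoxic list in CD8 T cells to 4.60 (LCMV), -0.073 (PFOA) and -0.31 (interaction). The exhaustion list in CD8 T cells moved to 2.39 (LCMV under PFOA), 0.044 (PFOA) and -0.37 (PFOA under LCMV) and the naive and memory list in CD8 T cells to -2.00 (LCMV), -1.12 (LCMV under PFOA), 0.73 (PFOA under LCMV) and 0.69 (interaction). The G2/M list in CD8 T cells moved to 2.46 (LCMV under PFOA), 0.26 (PFOA) and 0.0094 (PFOA under LCMV). Without cluster 6, the S phase list in CD8 T cells reversed to -0.055 (PFOA, from 0.41) and -0.21 (PFOA under LCMV, from 0.16) and the G2/M list in CD8 T cells to -0.31 (interaction, from 0.47). As a share of T cells, the CD8 share ratio moved to 1.99 (LCMV), 1.68 (LCMV under PFOA), 1.01 (PFOA) and 0.858 (PFOA under LCMV). Under the first version of the naming rule, the CD4 share ratio moved to 0.314 (LCMV) and 0.278 (LCMV under PFOA) and the CD8 share ratio to 216 (LCMV), 177 (LCMV under PFOA) and 0.580 (PFOA under LCMV). The interferon list in CD4 T cells moved to -0.12 (PFOA), -0.33 (PFOA under LCMV) and -0.096 (interaction) and the interferon list in CD8 T cells to 0.12 (PFOA under LCMV). The exhaustion list in CD8 T cells moved to -0.40 (PFOA under LCMV) and the naive and memory list in CD8 T cells to 0.82 (PFOA under LCMV). The S phase list in CD4 T cells moved to 0.24 (LCMV), 0.24 (LCMV under PFOA), -0.011 (PFOA), -0.024 (PFOA under LCMV) and -0.0042 (interaction) and the G2/M list in CD8 T cells to 0.012 (PFOA under LCMV). The cholesterol list in CD4 T cells moved to -0.90 (interaction). Under the first version of the naming rule, the CD8 share ratio reversed to 0.709 (PFOA, from 1.44), on 3 PFOA and 5 control cells. The naive and memory list in CD4 T cells reversed to 0.012 (LCMV, from -0.56). The S phase list in CD8 T cells reversed to -0.18 (PFOA under LCMV, from 0.16) and the glycolysis list in CD4 T cells to -0.19 (LCMV, from 0.88), -0.036 (LCMV under PFOA, from 0.35) and 0.095 (PFOA under LCMV, from -0.44). Under the first version of the naming rule the control and PFOA libraries held 5 and 3 CD8 T cells, under the minimum of 20. CD8 list medians that involve these libraries were not available, and the CD8 share ratios of 216 and 177 rested on these few cells. G2/M medians in CD4 T cells and NK cells and S phase medians in NK cells kept too few members of 200 or more UMIs, and G2/M medians in NK cells too few in thinned cells. Leaving out cluster 6 bears on CD8 T cells alone, and other resolutions and variable genes were run on class shares alone. Depth limits the uninfected libraries most, at 2596 and 2308 UMIs per median cell against 5573 and 5384, and genes with few UMIs there have wide counting intervals. Plasma cells of the control and PFOA libraries, 6 and 14, were too few for gene ratios.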

Other observations

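Of the tests in the 3 patterns below, those on NK cells, on Cr2 and S1pr3 and on RNA of other classes in CD8 T cells were chosen after the result was seen, and the others before.

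Thinned CD4 T cells with a Foxp3 UMI, a marker of regulatory T cells, were 7.92%, 6.81%, 6.19% and 7.09% in the control, PFOA, LCMV and PFOA + LCMV libraries. The B cell background was 0.305%, 0.262%, 0% and 0.0269% in the same order. Unthinned shares were 10.2%, 8.29%, 7.95% and 8.75%, at median depths of 2563, 2277, 3530 and 3687 UMIs in CD4 T cells and 2316, 1998, 4127 and 4500 in B cells. Cluster 10, which Foxp3, Ikzf2 and Ctla4 help to lead, held 17.5%, 15.1%, 30.1% and 29.1% of CD4 T cells in the same order, beside regulatory T cell list medians of 0.83 for LCMV against control and -0.47 for PFOA + LCMV against LCMV. In NK cells Mki67 stood at 33.0, 14.2, 216 and 263 CPM, and Ifi27l2a at 298 and 683 CPM in the LCMV and PFOA + LCMV libraries. S1pr5, a gene of mature NK cells, was 2.01-fold lower in the PFOA + LCMV than in the LCMV library.

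The type I interferon list was lower in B cells of the PFOA + LCMV library than of the LCMV library (median -0.41). The tables argue against a different mix of B cell clusters as the whole cause, with a median of -0.38 within cluster 1 and -0.46 within cluster 3, although clusters 8 and 18 were at -0.041 and -0.062. They also argue against depth, with -0.37 in thinned cells. Free RNA poor in interferon genes throughout the library stays open. The median in NK cells was 0.44 over 28 members, from 94 and 68 cells, but interferon RNA of the NK cells themselves could hide such a difference. The NK median was 0.15 over 10 members with thinned cells, and 0.38 with B cell RNA subtracted. That RNA made up 7.17% and 1.37% of NK cell UMIs by Cd79a. A lower interferon response of B cells under PFOA may be a candidate explanation. It stays open as untested, since PFOA exposure differed together with everything else between the 2 libraries, such as the course of infection.

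Marginal zone B cell genes, a list chosen after the values were seen, were higher in B cells of the PFOA + LCMV library than of the LCMV library (median 0.73). The tables argue against depth, with 0.55 in thinned cells. Free RNA of all 8 genes stays open, since their summed level in CD8 T cells of the PFOA + LCMV library was 36.1% of that in B cells, but for Cr2 and S1pr3 it was 3.70%, which argues against free RNA as their source. Cluster 3, with Cr2 among its leading genes, held 34.6% against 15.6% of B cells, and medians within clusters 1, 3, 8 and 18 were 0.072, 0.29, 0.45 and 0.21, but such genes helped to form the clusters. A larger part of marginal zone B cells among B cells may be a candidate explanation, untested and confounded with the library.

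Naive and memory genes were higher in CD8 T cells of the PFOA + LCMV library than of the LCMV library (median 0.39). The tables argue against depth, with 0.65 in thinned cells, and against RNA of B cells or CD4 T cells in this class, with 0.37 and 0.56 after subtraction of each, although B cell RNA by Cd79a was 3.39% against 1.49% of UMIs. A larger fraction of less activated cells may be a candidate explanation, and the median was 0.023 over 16 members within cluster 5, the Klrg1 cluster, and 0.25, -0.14 and 0.13 within clusters 6, 15 and 27. This explanation cannot be told apart from a difference within cells, since the listed genes helped to form the clusters. PFOA exposure itself stays open as untested.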
